A study of Caenorhabditis elegans with 32 samples.

How the data were processed

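The mRNA of whole Caenorhabditis elegans adults was measured by poly-A selected RNA sequencing in 20 libraries, and chromatin immunoprecipitation of histone H3 and of H3 trimethylated at lysine 36 was made in a further 12 samples, which were not analysed here. All animals carried the temperature-sensitive allele glp-1(e2141), which removes most of the germline at the restrictive temperature, and were collected at day 2 or day 12 of adulthood. The mRNA libraries fall into 10 groups of 2, namely untreated glp-1 animals grown in parallel with the chromatin samples, glp-1 animals serving as control of a met-1 mutant, met-1(n4337); glp-1(e2141) double mutants, and glp-1 animals labelled as given L4440 (the usual empty vector of feeding RNA interference) or met-1 RNA interference, each at both ages. Groups and replicate numbers were taken from the sample labels. The labels tie the replicates of the untreated animals to differently numbered chromatin replicates. They do not state for any group whether replicates were separate cultures. Every p-value therefore measures only the spread between these samples, which may be technical.

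The authors deposited 4 tables. FPKM, fragments per length of transcript and per number of mapped fragments, is the unit of the control, mutant and isoform tables, per the file headers. The RNA interference table holds 1 value per library for 8 libraries. Its column names mention uniquely placed accepted hits but give no unit, per the file headers. Its values were taken as FPKM because the processing notes list Cuffdiff. The other tables hold 1 FPKM value per age for both libraries together, as deposited by the authors, so no spread between libraries can be computed from them. The status columns of the control and mutant tables, deposited by the authors, give OK, HIDATA or FAIL for each FPKM estimate, per the file headers. The log2 fold change of the isoform table was deposited by the authors and equals the log2 ratio of its FPKM values within 4.8e-05, except that it is written as 0 in the 388 transcripts with an FPKM of 0 at one age. The q-value in the same table was deposited by the authors, its test is not given in the sources used here, and its smallest value, 9.44e-21, is shared by 732 transcripts. CASAVA 1.8, BWA, TopHat, TopHat2 and Cuffdiff are listed, with no role or order, per the submitters' processing notes. The genome build, the annotation, the strandedness of the counting and the way libraries were scaled to each other are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be separated, and members of families with near-identical copies, such as collagens, major sperm proteins and histones, are uncertain.

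The RNA interference, control and mutant tables share 46971 RefSeq transcripts, of which 25913 have protein-coding and 21058 non-coding identifiers. The isoform table holds 16422 protein-coding transcripts, of which 15330 are also in the other tables. Symbols were matched through the RefSeq identifiers for 44265 of 46971 and 15394 of 16422 transcripts. An FPKM of 0 can be a failed estimate: 1077 transcripts in 1 stretch of chromosome IV, from 380017 to 4526957 in the coordinates of the tables, have the status HIDATA in all 4 status columns, and the same transcripts are listed at 0 in 6 of the 8 RNA interference libraries. The 1112 transcripts with any status other than OK were left out of every test, among them 4 of the 6 vitellogenin transcripts. The RNA interference table has no status column, so an estimate that failed only there would have stayed in. Where a group is listed at 0, FPKM values are given and no fold change.

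The tables give no read totals, so depth was judged from the steps between low values. This gave relative reads of 0.355 to 1.298 for the 8 RNA interference libraries, with the second met-1-labelled library of day 12 set to 1.0. Depth of the other tables is unknown. No pair among the 8 libraries held an identical set of values.

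Transcripts were tested with limma 3.58.1 (lmFit and eBayes with trend, two-sided) in R 4.3.3 on log2(FPKM + 1), with 4 groups of 2 libraries in 1 fit. Tested transcripts had an FPKM of at least 1 in at least 2 libraries, which left 18572, and calls were made at a Benjamini-Hochberg adjusted p below 0.05. Changes are on the log2(FPKM + 1) scale, which understates the change of low transcripts. Between day 2 and day 12 the median transcript of the RNA interference table moved by 0.46 in L4440 and 0.48 in met-1-labelled animals, against 0.00 in the control, −0.01 in the mutant and −0.08 in the isoform table. Age changes of single transcripts in the RNA interference table are therefore printed relative to the median, from a fit with every library centred to one median, and "rose" and "fell" refer to calls in that fit. Comparisons between arms are printed as deposited, since the median there moved by 0.01 at day 2 and 0.02 at day 12.

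Gene lists were fixed before the data were examined: vitellogenins, cuticle collagens and hypodermis structural genes, intestine markers, body wall muscle and sarcomere genes, pharynx markers and abu genes, neuron markers, neuropeptides of the FMRFamide-like family, germline and oocyte markers, sperm markers, ribosomal proteins, proteasome subunits, mitochondrial oxidative phosphorylation, vacuolar ATPase subunits, lysosomal and intestinal proteases, heat shock and protein folding, small heat shock proteins, antioxidant and metal response, xenobiotic metabolism, innate immunity effectors, insulin signalling components and insulin-like peptides, lipid metabolism, F-box and MATH domain genes, hedgehog-related genes, nuclear hormone receptors, histone genes, histone methylation enzymes and readers, and small RNA pathway genes. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. List medians are given relative to the median transcript. In the age comparisons of the RNA interference table camera was run on the values as deposited. The list medians and member counts printed beside it there come from the centred fit. In tables without library values no test was made, and a transcript was counted as higher or lower when it moved by at least 1 on the log2(FPKM + 1) scale. Counts within lists there were taken relative to the median transcript. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these tables and is not a p-value. Tables were made separately, so tests between groups stay within a table, and levels from different tables are set side by side only as descriptions. Transcripts that moved the same way in all 5 age comparisons, by at least 1 relative to the median transcript, were counted across tables. Their share in each list was tested with Fisher's exact test (two-sided) over transcripts, which are not independent replicates.

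Transcripts named in the text follow a rule: met-1, the 5 largest rises and 5 largest falls past the threshold whose groups do not overlap, and for each list up to 4 members past the threshold with the largest change, or up to 2 with the highest mean FPKM where none passed. In the isoform table the rule used the authors' log2 change and q below 0.05, and in the control and mutant tables the size of the change. Other transcripts are named as chosen after their values were seen.

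The procedures were tested on simulated data. In each of 5 runs on 18572 transcripts, 200 transcripts drawn anew were changed, some by 1 and the others by 2 on the log2 scale. For L4440 ageing limma recovered 6.0% of those changed by 1 and 41.2% of those changed by 2, with 2.4 false calls on average. For ageing in met-1-labelled animals these values were 5.4%, 42.0% and 0.8. Simulations of the 3 comparisons without changed transcripts gave 0 calls, with normal noise around 1 mean per transcript. Many transcripts called between the arms are instead listed at 0 in one arm. In the measured values, splits that mix the arms gave 37 and 9 calls at day 2 and 77 and 59 at day 12. The simulated 0 is therefore no rate of false calls between the arms. On the same 18572 transcripts of L4440 ageing, camera called a changed list of 50 members in 5 of 5 runs and 0 of 100 unchanged lists. In the control table, with 17692 transcripts and lists of 40 members, 3 of 100 unshifted lists and 98 of 100 lists shifted by 1 fell outside the middle 95% of random lists. All simulated transcripts varied independently of each other. Members of the real lists need not, with an estimated correlation of 0.789 for ribosomal proteins in L4440 ageing. The simulated lists therefore do not give the rate of false list calls in these data.

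Alternatives were a pseudocount of 0.1, no filter or a filter at 5 FPKM, quantile normalization, centring, a replicate block, eBayes without trend, only the 2 compared groups in the fit, a size threshold of 1, and leaving out each library. Chosen after seeing the data were keeping transcripts with failed estimates, summing FPKM per gene, protein-coding transcripts only, transcripts alone in their locus only, and scaling to the same summed FPKM. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.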

Results

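The data describe mRNA of whole glp-1(e2141) animals, which lack most of their germline, at day 2 and day 12 of adulthood, in 20 libraries of 10 groups with 2 libraries each. The series asks how histone H3 lysine 36 trimethylation and its methyltransferase gene met-1 relate to change of expression with age. Library values exist for the 8 libraries of the RNA interference experiment, in which animals were labelled as given L4440 or met-1 RNA interference. These libraries list 14577 to 17234 transcripts at an FPKM of at least 1. Their relative read numbers at day 2 were 1.24 and 1.209 in L4440 and 1.193 and 1.236 in met-1-labelled libraries. At day 12 they were 1.051 and 0.355 in L4440 and 1.298 and 1.0 in met-1-labelled libraries, so that the second L4440 library of day 12 was the shallowest. The correlation between the 2 replicates, taken across transcripts, was 0.878 for L4440 and 0.91 for met-1-labelled animals at day 12, and 0.93 and 0.929 at day 2.

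The targeted gene met-1, on chromosome I, was higher rather than lower in the libraries labelled met-1 RNA interference. At day 2 the FPKM summed over its transcripts NM_182042 and NM_058939 was 7.80 and 5.03 in the L4440 libraries and 13.03 and 27.5 in the libraries labelled met-1 RNA interference. At day 12 the sums were 10.7 and 29.8 in L4440 and 80.1 and 57.1 in the libraries labelled met-1 RNA interference. Transcript NM_182042 differed between arms by 1.77 ± 0.71 on the log2 scale at day 2 (SE, limma adjusted p = 1) and by 1.92 ± 0.71 at day 12 (adjusted p = 0.439). An exact permutation test within ages, two-sided over 36 arrangements, gave a mean difference of 1.66 for the sum with p = 0.0556, the smallest p this design allows. In the separately made tables the sum was 5.41 and 6.34 FPKM in control animals and 6.67 and 4.79 in met-1 mutants at day 2 and day 12, values from both libraries together. The met-1 level therefore goes against the labels of the RNA interference arms, which alone does not show the labels to be wrong. Reads from the fed double-stranded RNA might also raise it, which is taken up below and was not decided. Every direction between arms given here is drawn from those labels. A mutation that leaves mRNA in place would not be seen in the mutant values.

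**Figure D1:**
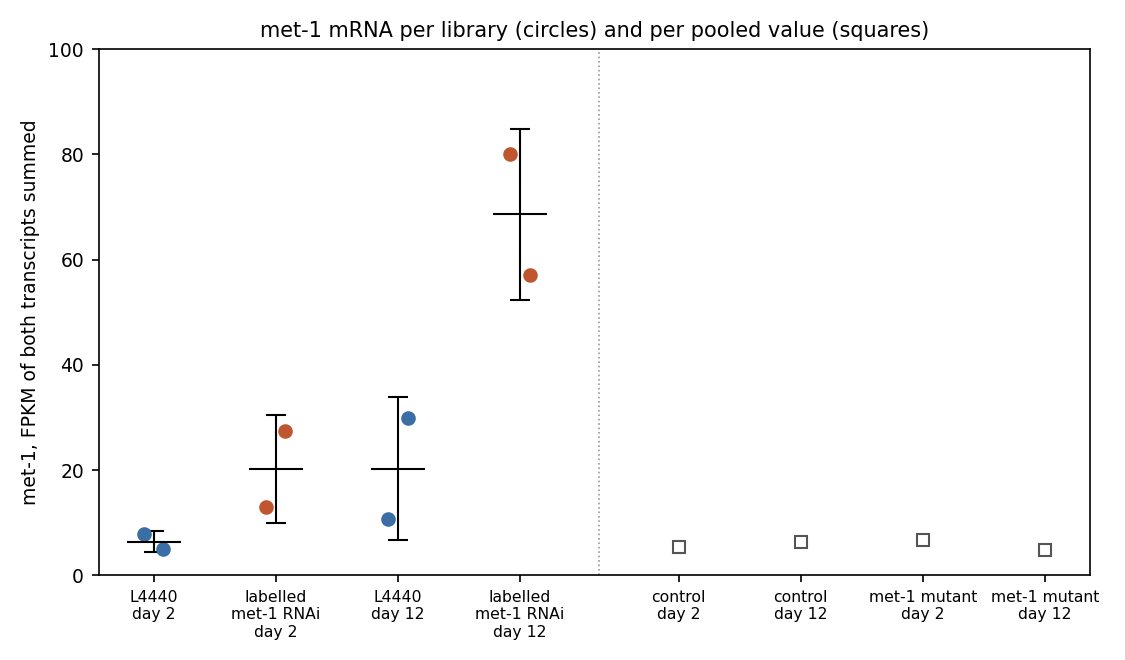
FPKM of met-1, both transcripts summed, in the 8 libraries of the RNA interference experiment (circles, with the mean as a horizontal line and the SD of 2 libraries as the error bar) and as the authors' single value per age in the control and mutant tables (squares, made separately). At day 12 the libraries labelled met-1 RNA interference stand at 80.1 and 57.1, above the L4440 libraries at 10.7 and 29.8.

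In L4440 animals, day 12 was compared with day 2 for change of expression with age. Expression of acdh-1 (NM_059470, chromosome I), an acyl-CoA dehydrogenase, fell from 1948 ± 282 to 2.46 ± 1.42 FPKM (SD, n = 2 libraries per age), a log2 change of −9.72 ± 0.30 (SE) relative to the median transcript. The gene pud-3 (chromosome V) fell, with a change of −11.31 ± 0.56. The lysozyme gene ilys-5 (chromosome X) and the transcript NM_067008 (chromosome III) also fell, with changes of −9.98 ± 0.49 and −9.85 ± 0.91. The non-coding transcript C09D4.8 was listed at 1615 and 1654 FPKM at day 2 and at 0 at day 12. The largest rises were in transcripts listed at 0 at day 2, among them uig-1 (1147 and 1193 FPKM at day 12), R09D1.16 (1247 and 820.2), F30H5.4 (459.6 and 816) and F07G11.10 (312 and 923). T24B8.17 stood at 305 and 2711 FPKM at day 12 and did not pass relative to the median (adjusted p = 0.0638). Of 18572 transcripts tested with limma, 4193 were higher and 1352 lower at day 12 as deposited (75.6% higher), and 1260 rose and 2210 fell once the libraries were centred to one median (36.3% higher). With quantile normalization the split was 1743 to 1961 (47.1% higher), and with equal summed FPKM 1553 to 1779 (46.6% higher). The 5545 calls as deposited became 3175 and 2846 without the first or second L4440 library of day 12, and 3250 and 3174 without the first or second of day 2.

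**Figure D2:**
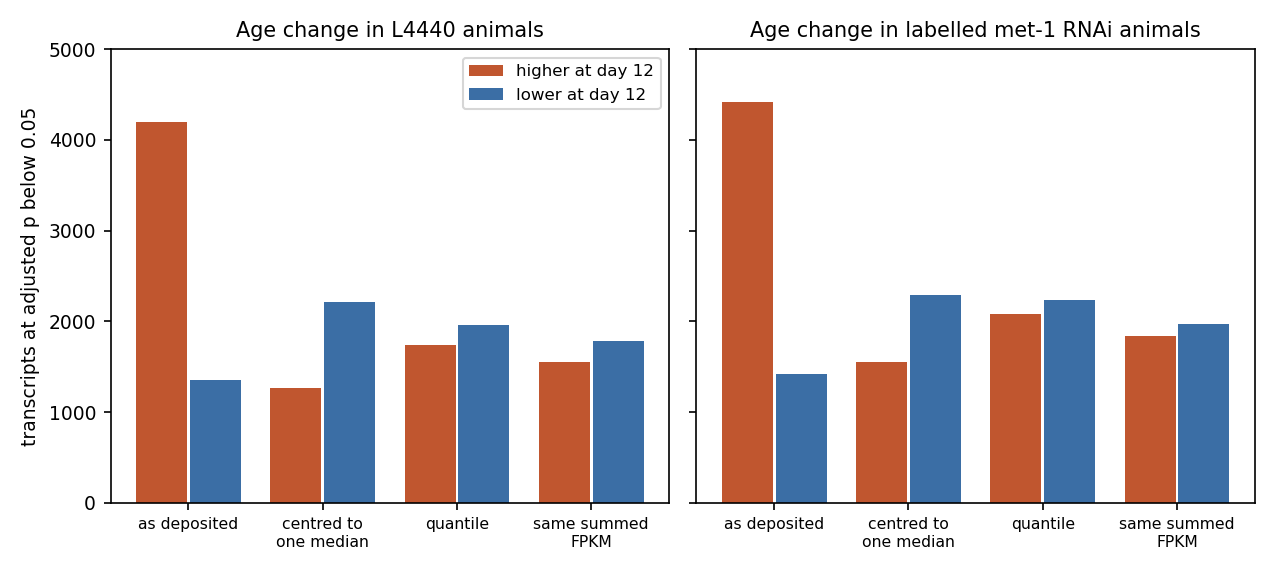
Number of transcripts at an adjusted p below 0.05 that were higher (orange bars) or lower (blue bars) at day 12 than at day 2, in L4440 animals (left) and in animals labelled met-1 RNA interference (right), under 4 scalings of the libraries. Higher calls outnumber lower ones only for the values as deposited, with 4193 against 1352 in L4440 and 4417 against 1418 in met-1-labelled animals.

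Among the lists that fell in L4440 animals, 51 of 91 cuticle collagen and hypodermis transcripts fell and 2 rose (61 and 2 adjusted over the list alone), with a median of −1.72 (camera adjusted p = 6.5e-25, and adjusted p = 0.0170 with an estimated correlation). The cuticle collagen col-20 fell from 3505 ± 30.2 to 5.68 ± 0.449 FPKM (SD, n = 2). The collagen gene col-139 fell from 884 ± 179 to 6.72 ± 1.84 FPKM, and col-80 and col-98 changed by −7.78 ± 0.82 and −6.93 ± 0.52 (log2, SE). Collagens share sequence, so single members are uncertain. Of 37 transcripts of mitochondrial oxidative phosphorylation, 30 fell and 0 rose (33 and 0 adjusted over the list alone), with a median of −1.19 (adjusted p = 1.0e-14, and adjusted p = 0.457 with an estimated correlation). The ATP synthase subunit gene atp-5 fell from 879 ± 33.5 to 438 ± 16.8 FPKM and the succinate dehydrogenase gene sdhb-1 from 222 ± 0.283 to 111 ± 3.44 (SD, n = 2). The cytochrome oxidase gene cox-7C changed by −1.69 ± 0.21 and the ATP synthase gene asg-2 by −1.51 ± 0.17. Of 121 lipid metabolism transcripts 46 fell and 1 rose (55 and 6 adjusted over the list alone, median −0.68, adjusted p = 5.3e-08, and adjusted p = 0.116 with an estimated correlation). The riser was cpt-4, a carnitine palmitoyltransferase gene, at 4.74 ± 2.2 and 198 ± 12.4 FPKM. In body wall muscle and sarcomere genes 24 of 64 fell and 1 rose (25 and 1 adjusted over the list alone, median −0.54, adjusted p = 9.4e-05, and adjusted p = 0.457 with an estimated correlation). The troponin T transcript NM_001029532 of tnt-2 fell from 234 ± 65.2 to 51.6 ± 14.7 FPKM. Of 23 vacuolar ATPase transcripts 14 fell and 1 rose (16 and 1 adjusted over the list alone, median −0.78, adjusted p = 0.00105, and adjusted p = 0.457 with an estimated correlation). The proton pump genes vha-5 and vha-12 changed by −1.38 ± 0.11 and −1.26 ± 0.14, and vha-18 rose by 1.55 ± 0.22.

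Detoxification, protease and immunity lists held members moving both ways in L4440 animals. Of 177 xenobiotic metabolism transcripts 53 fell and 21 rose (66 and 26 adjusted over the list alone, median −0.64, adjusted p = 5.8e-04, and adjusted p = 0.457 with an estimated correlation). The glutathione S-transferase genes gst-10 and gst-4 fell from 519.6 ± 178 to 21.8 ± 4.58 and from 523 ± 117 to 50.7 ± 4.7 FPKM (SD, n = 2). Glucuronosyltransferase ugt-53 changed by −4.48 ± 0.36, whereas ugt-8 rose by 3.42 ± 0.40 and the cytochrome P450 gene cyp-13B1 by 3.37 ± 0.47. Of 37 antioxidant and metal response transcripts 12 fell and 2 rose (12 and 2 adjusted over the list alone, median −0.60, adjusted p = 6.7e-04, and adjusted p = 0.457 with an estimated correlation). Among them the superoxide dismutase gene sod-1 and the glutathione peroxidase gene gpx-5 changed by −2.37 ± 0.18 and −2.36 ± 0.15. Of 203 innate immunity transcripts 59 fell and 15 rose (71 and 20 adjusted over the list alone), with a median of −0.30 relative to all transcripts but 0.22 as deposited (adjusted p = 3.9e-04, and adjusted p = 0.457 with an estimated correlation). The saposin-like gene spp-17 fell from 2813 ± 14.1 to 7.61 ± 0.908 FPKM and spp-9 rose from 30.1 ± 0.35 to 2990.3 ± 1.26 (SD, n = 2). In the protease list 8 of 23 fell and 2 rose (12 and 2 adjusted over the list alone, median −0.89, adjusted p = 0.0129, but adjusted p = 0.133 with quantile normalization and 0.52 with an estimated correlation). The aspartyl protease gene asp-18 rose from 0.91 ± 0.508 to 865 ± 36 FPKM and the cathepsin B-like gene cpr-2 from 0.797 ± 1.005 to 536 ± 239. The protease genes asp-13 and cpr-1 fell, with changes of −3.52 ± 0.25 and −3.24 ± 0.47.

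Lists called upward in L4440 animals were ribosomal proteins, FMRFamide-like neuropeptides, insulin genes and, with members moving both ways, F-box genes. Of 87 ribosomal protein transcripts 15 rose and 0 fell (60 and 0 adjusted over the list alone, median 0.83, adjusted p = 1.7e-12, and adjusted p = 0.507 with an estimated correlation). Among them rsl-24D1 rose from 76.4 ± 8.22 to 401 ± 12.5 FPKM. Of 36 neuropeptide transcripts 10 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.98, adjusted p = 3.9e-04, and adjusted p = 0.457 with an estimated correlation). FMRFamide-like flp-5 rose from 18.3 ± 5.54 to 139.96 ± 17.1 FPKM and flp-21 from 36.9 ± 14.6 to 251 ± 18 (SD, n = 2). Of 49 insulin transcripts 13 rose and 2 fell (15 and 3 adjusted over the list alone, median 0.84, adjusted p = 0.0425, and adjusted p = 0.457 with an estimated correlation). The insulin-like peptide gene ins-20 rose by 5.78 ± 0.46 and ins-11 by 2.99 ± 0.49, and ins-22 rose from 4.47 ± 4.71 to 87.3 ± 19.5 FPKM. Of 194 F-box and MATH domain transcripts 20 rose and 11 fell (17 and 10 adjusted over the list alone, median 0.17, adjusted p = 0.0288, but adjusted p = 0.0804 with quantile normalization and 0.55 with an estimated correlation). The F-box gene fbxa-24 rose from 4.05 ± 0.952 to 187 ± 30.7 FPKM.

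The remaining lists did not pass in the main fit of L4440 animals. Intestine markers had 6 of 24 falling and 1 rising (6 and 1 adjusted over the list alone, median −0.43, or 0.10 as deposited, adjusted p = 0.0767). The gut esterase gene ges-1 fell from 162 ± 56.1 to 47.7 ± 2.73 FPKM and the peptide transporter gene pept-1 rose from 15.4 ± 2.07 to 63.1 ± 18.1. Hedgehog-related genes had 11 of 45 falling and 5 rising (14 and 7 adjusted over the list alone, median −0.32, or 0.21 as deposited, adjusted p = 0.0767), with grd-5 changing by −5.39 ± 0.43 and the patched-related ptr-22 by 4.43 ± 0.24. Heat shock and folding genes had 6 of 80 rising and 5 falling (6 and 4 adjusted over the list alone, median 0.04, camera adjusted p = 0.0678). This list passed upward with the replicate block and with quantile normalization (camera adjusted p = 0.0496 and 0.02345). It did not with an estimated correlation (adjusted p = 0.55). The chaperone gene hsp-90 rose from 283 ± 88.6 to 2139.7 ± 126 FPKM. In the small heat shock list 2 of 15 rose and 3 fell (2 and 3 adjusted over the list alone, median −0.33, or 0.20 as deposited, adjusted p = 0.342). Germline markers had 3 of 29 rising and 0 falling (2 and 0 adjusted over the list alone, median 0.10, adjusted p = 0.079), with the oocyte gene pos-1 rising by 2.72 ± 0.32. Sperm markers had 4 of 31 rising and 3 falling (4 and 7 adjusted over the list alone, median −0.53, adjusted p = 0.20), with spe-11 rising by 3.22 ± 0.22. Neuron markers had 4 of 51 rising and 5 falling (4 and 6 adjusted over the list alone, median 0.15, adjusted p = 0.364). The G protein gene odr-3 rose from 0.742 ± 0.153 to 10.2 ± 0.287 FPKM. Nuclear hormone receptors had 9 of 236 rising and 14 falling (3 and 6 adjusted over the list alone, median 0.00, adjusted p = 0.244), with nhr-235 changing by −3.20 ± 0.44. Histone genes had 2 of 28 rising and 2 falling (2 and 2 adjusted over the list alone, median −0.55, adjusted p = 0.146), with his-74 changing by 2.35 ± 0.32 and his-38 by −3.19 ± 0.18. Of 56 histone methylation transcripts 4 rose and 0 fell (2 and 0 adjusted over the list alone, median −0.03, or 0.49 as deposited, adjusted p = 0.142). The H3K36 methyltransferase gene mes-4 rose from 0.571 ± 0.067 to 20.5 ± 13 FPKM. Small RNA pathway genes had 1 of 45 rising, the RNA polymerase gene rrf-2 by 2.39 ± 0.18, and 1 falling (1 and 0 adjusted over the list alone, median −0.05, or 0.47 as deposited, adjusted p = 0.646). Proteasome subunits had 0 of 35 rising and 1 falling (0 and 1 adjusted over the list alone, median −0.15, or 0.38 as deposited, adjusted p = 0.408). Pharynx markers had 0 of 21 called either way (0 adjusted over the list alone, median 0.13, adjusted p = 0.408). Of 6 vitellogenin transcripts 2 were tested, too few for a list test. Median and test differed in sign for proteasome, histone methylation and small RNA genes, with medians of −0.15, −0.03 and −0.05 against a test direction upward. For nuclear hormone receptors the mean was −0.06 against an upward test. These medians and this mean are from the centred fit. The tests used the values as deposited, where the proteasome, histone methylation and small RNA medians were 0.38, 0.49 and 0.47.

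Ageing of the animals labelled met-1 RNA interference gave 1550 rises and 2291 falls relative to the median (40.4% higher), against 4417 and 1418 as deposited (75.7% higher). Expression of acdh-1 fell from 1420.3 ± 282 to 1.07 ± 0.007 FPKM (SD, n = 2 per age), a log2 change of −9.90 ± 0.30 (SE). The genes pud-3, ilys-5 and the collagen gene col-20 fell, with changes of −9.96 ± 0.56, −9.28 ± 0.49 and −8.18 ± 1.11. Non-coding R09D1.16 was listed at 0 at day 2 and at 2076 and 3496 FPKM at day 12. Collagens fell in 51 of 91 transcripts and rose in 0 (57 and 1 adjusted over the list alone, median −1.61, adjusted p = 3.9e-22, and adjusted p = 0.0214 with an estimated correlation). Oxidative phosphorylation had 33 of 37 falling and 0 rising (34 and 0 adjusted over the list alone, median −1.18, adjusted p = 2.6e-16, and adjusted p = 0.465 with an estimated correlation). In this list cox-6C and asg-2 changed by −1.68 ± 0.21 and −1.64 ± 0.17. Lipid metabolism had 45 falling and 4 rising (56 and 5 adjusted over the list alone, median −0.80, adjusted p = 3.8e-09, and adjusted p = 0.0902 with an estimated correlation). The fatty acid elongase gene elo-6 fell from 2669 ± 429 to 154 ± 47.4 FPKM. Ribosomal proteins had 25 rising and 0 falling (77 and 0 adjusted over the list alone, median 0.90, adjusted p = 4.0e-13, and adjusted p = 0.548 with an estimated correlation). The other lists called were muscle (median −0.52), vacuolar ATPase (−0.57), proteases (−0.77), antioxidant (−0.67), xenobiotic (−0.59) and immunity genes (−0.26, but 0.23 as deposited) downward and neuropeptides (0.66) and heat shock genes (0.11) upward. Their highest adjusted p was 0.0379, and each was lost with an estimated correlation (adjusted p = 0.465 to 0.577). Protease genes cpr-2 and asp-18 rose by 7.54 ± 0.69 and 4.32 ± 0.55, and the antimicrobial gene cnc-1 by 6.58 ± 1.05. Also rising were ins-20 by 6.32 ± 0.46 and ptr-22 by 4.96 ± 0.24, and the small heat shock gene hsp-12.6 rose from 5.51 ± 0.236 to 282 ± 166 FPKM. The 5835 calls as deposited became 3237 and 3037 without the first or second met-1-labelled library of day 12, and 2477 and 2762 without the first or second of day 2.

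**Figure D3:**
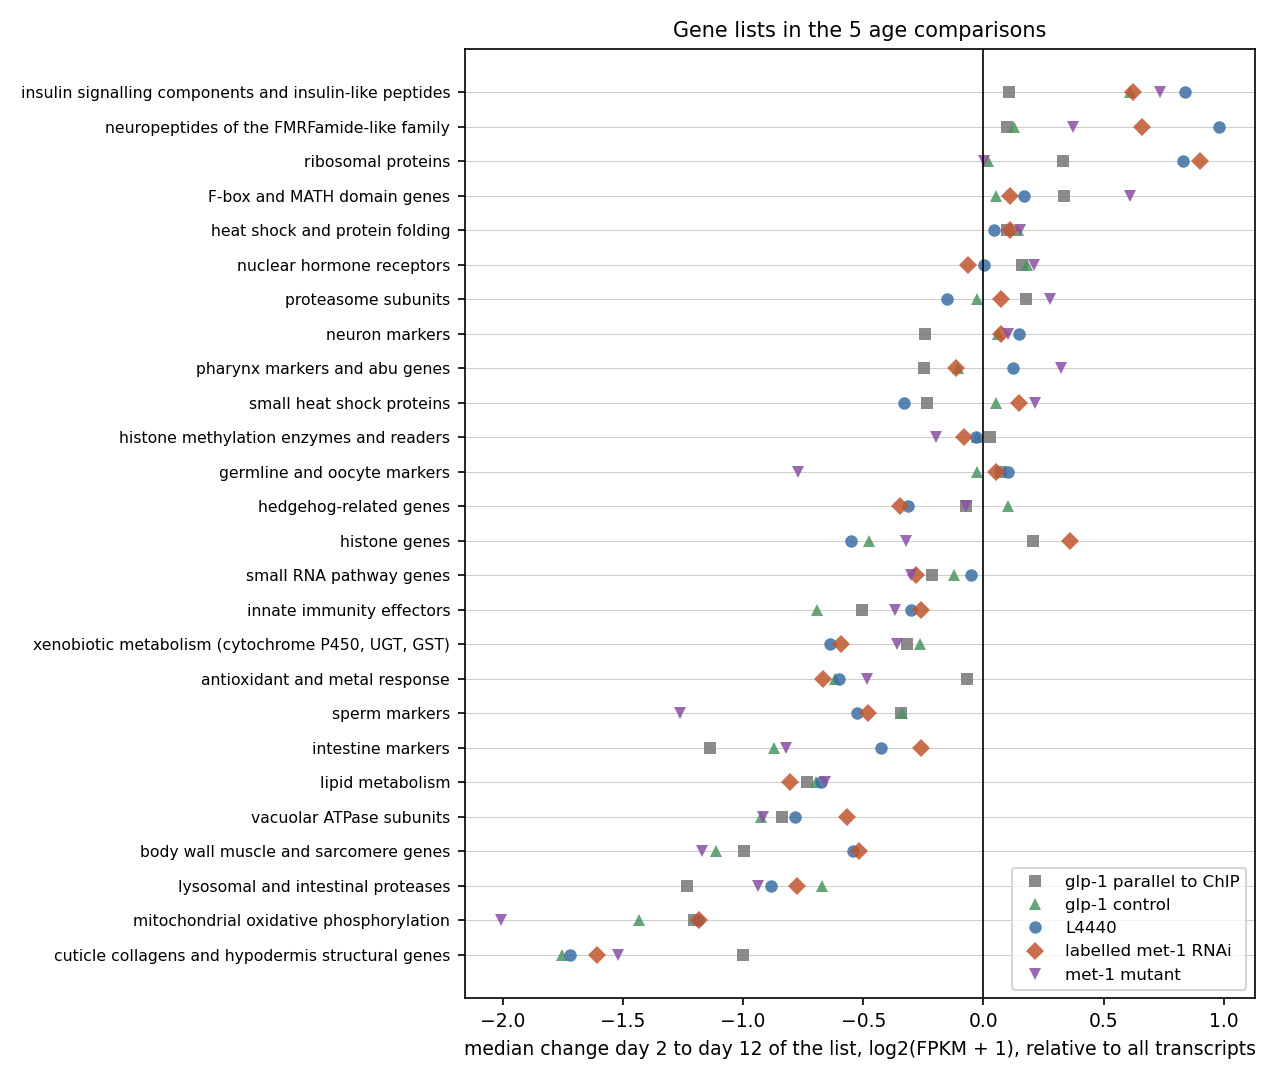
Median change of each gene list from day 2 to day 12, on the log2(FPKM + 1) scale and relative to all transcripts of the same table, in the 5 age comparisons (symbols), with collagens below 0 in all 5 and reaching −1.75 in the control. Before centring, the L4440 medians of intestine, immunity, hedgehog-related, small heat shock, proteasome, histone methylation and small RNA genes lie above 0 instead of below, as in met-1-labelled animals do those of intestine, immunity, hedgehog-related, pharynx, sperm, nuclear receptor, histone methylation and small RNA genes.

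Whether the age change differed between the arms was tested as an interaction, with directions drawn from labels that met-1 goes against. The collagen transcript NM_001270293 of col-184 was 40.4 and 29.3 FPKM at day 2 and 0 at day 12 in L4440, and was above 0 in all 4 met-1-labelled libraries, at 5.43 and 7.02 at day 12 (adjusted p = 0.0185). C01A2.9 was 8.47 and 8.68 FPKM at day 2 and 0 at day 12 in L4440, and 0 at day 2 and 32.3 and 36.7 at day 12 in met-1-labelled libraries (adjusted p = 0.000952). Among the other largest differences the non-coding transcripts F40E3.9, F18H3.7 and E02C12.17 were higher (adjusted p = 0.000425, 0.000952 and 0.0185) and Y51A2D.26, F21F12.2, B0511.18 and F37B12.8 lower, and the coding transcript K09E3.4 was also lower. E02C12.17 was 7.73 and 7.93 FPKM at day 2 and 0 at day 12 in L4440, and 0 at day 2 and 14.8 and 38.3 at day 12 in met-1-labelled libraries. In C09D4.8 the difference came from day 2, since it was listed at 0 in all 4 libraries of day 12. Of 18572 transcripts 50 had a higher and 20 a lower age change in met-1-labelled animals, and 1065 had an unadjusted p below 0.05 against 929 given by chance. Histone genes were called upward (median 0.67, adjusted p = 0.00541, and adjusted p = 0.609 with an estimated correlation) with 0 members called. Without 1 library the 70 calls became 17 or 16 (L4440, day 2), 11 (second L4440, day 12), 74 (first L4440, day 12, of which 24 were among the 70), 14 or 11 (met-1-labelled, day 12) and 10 or 9 (met-1-labelled, day 2), and with a 5 FPKM filter 9.

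Between the arms at day 2 the transcripts called were mostly non-coding and listed at 0 in one arm. The Piwi gene prg-1 (NM_059720, chromosome I), which binds germline small RNAs, was 37.6 and 40.5 FPKM in L4440 and 15.1 and 13.7 in the libraries labelled met-1 RNA interference, a change of −1.38 ± 0.12 (SE, n = 2 per group, adjusted p = 0.0320). The largest differences were C09D4.8 (1615 and 1654 against 0, adjusted p = 4.9e-05) and linc-78 (14.4 and 29.5 against 0, adjusted p = 0.0233) in favour of L4440, with C11G10.11 (13.1 and 13.4), T12D8.11 (11.3 ± 0.195, SD, n = 2) and F53B3.8 (7.73 and 15.8) also listed at 0 in met-1-labelled libraries. Listed at 0 in L4440 were smy-1 (148 and 143 FPKM in the other arm), B0511.18 (160.4 and 60.5), F37B12.8 (68.1 and 132), NR_101678 (53.2 and 88.6) and T03E6.13 (103 and 33.1). Chosen after their values were seen, K08D8.12 was 2.99 and 2.48 FPKM in L4440 and 24.8 and 30.8 in met-1-labelled libraries (adjusted p = 0.0117). Likewise R02F2.1 was 12.5 and 13.4 against 0 and 0.376 (adjusted p = 0.0233), and the non-coding fmo-4 transcript NR_069899 was 0.017 and 0.013 against 5.17 and 8.05 (adjusted p = 0.0447, but 0.0504 once centred). Of 30 calls 16 were higher and 14 lower, 25 lay in transcripts with one arm at 0, 3 lay in genes with more than 1 listed transcript, of which 0 had their gene called with summed FPKM, and 635 transcripts had an unadjusted p below 0.05 against 929 by chance. Ribosomal proteins (median −0.25, adjusted p = 2.0e-07) and immunity genes (median −0.17, adjusted p = 0.025) were called downward with 0 members called (0 adjusted over the list alone), and both were lost with an estimated correlation (adjusted p = 0.941), immunity also with quantile normalization (adjusted p = 0.116). Nearly all of these 30 calls were lost when any 1 library of day 2 was left out, whichever arm it came from.

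At day 12 prg-1 was again lower in the libraries labelled met-1 RNA interference, at 46.1 and 43.6 FPKM in L4440 against 19.7 and 20.9 (−1.11 ± 0.12, SE, n = 2, adjusted p = 0.0337). Non-coding F40E3.9 (1548 and 2002 FPKM), F18H3.7 (425 and 552), smy-1 (136 and 707), F26D11.18 (109.5 and 284) and H40L08.5 (31.4 and 81.7) were listed at 0 in L4440. Y51A2D.26 (290.1 and 429), K09E3.4 (107 and 159), F21F12.2 (59.2 and 175), B0350.72 (40.6 and 240.2) and T21B4.18 (34.3 and 202) were listed at 0 in met-1-labelled libraries. The F-box gene fbxa-170 was 0.614 and 0.227 FPKM in L4440 against 6.72 and 6.30, and the MATH domain transcript NM_001269368 of math-33 was 0.011 and 0.007 against 23.4 and 10.4 (adjusted p = 0.0296 and 0.0407). Chosen after their values were seen, sysm-1 was 558 and 529.98 FPKM in L4440 and 85.3 and 109.96 in met-1-labelled libraries (−2.48 ± 0.20, adjusted p = 0.00916). The neuropeptide transcript NM_001270134 of nlp-7 was 26.2 and 43.1 against 0.007 and 0.037 (adjusted p = 0.00519), and the calcium pump transcript NM_066985 of sca-1 was 0.011 and 0.015 against 14.7 and 13.4 (adjusted p = 0.00479). With FPKM summed over all transcripts of a gene, math-33 and sca-1 differed between arms by −0.17 and −0.0021, so these 2 calls are of single transcripts and not of the gene. Of the 14 called transcripts in genes with more than 1 listed transcript, 1 had its gene called in the same direction with summed FPKM. Transcript NM_001026740 of egl-27 was 5.03 and 5.19 against 0.002 and 0.003, and scl-11 differed by −3.16 ± 0.32 (adjusted p = 0.0156 and 0.0218). The fatty acid desaturase gene fat-2 was 5116 and 4172 FPKM against 2006 and 2073 and did not pass (adjusted p = 0.105). Of 92 calls 57 were higher and 35 lower, with one arm at 0 in 68, and 1974 transcripts had an unadjusted p below 0.05. The shallowest library moved the count to 61 when left out, the first L4440 library of day 12 to 169, and the first or second met-1-labelled one to 12 or 11, and with only the 2 compared groups in the fit 4 calls were made.

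Gene lists between arms at day 12 gave 11 calls, none of which held with an estimated correlation. Proteasome subunits (median 0.24, adjusted p = 0.0016), small heat shock proteins (0.40, adjusted p = 0.0137) and histone genes (0.44, adjusted p = 0.0223) were called higher in the libraries labelled met-1 RNA interference. Proteases (−0.23, adjusted p = 0.0022), ribosomal proteins (−0.17, adjusted p = 0.0101), oxidative phosphorylation (−0.17, adjusted p = 0.0102), neuropeptides (−0.24, adjusted p = 0.0161), lipid metabolism (−0.08, adjusted p = 0.0321), nuclear hormone receptors (−0.08, adjusted p = 0.0364), xenobiotic metabolism (−0.12) and F-box genes (−0.11, both adjusted p = 0.0408) were called lower. With an estimated correlation ribosomal proteins had adjusted p = 0.808 and the others adjusted p = 0.798. Ribosomal proteins and lipid metabolism were also lost with quantile normalization (adjusted p = 0.630 and 0.0547), and xenobiotic metabolism with the replicate block (adjusted p = 0.0601). Members called were 2 F-box and MATH domain transcripts, both higher and so against the direction of their list, and adjusted over the list alone 2 proteases fell and 1 histone rose.

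In glp-1 control animals, where each age has 1 value for both libraries and no test is possible, collagen and lipid metabolism lists were lower at day 12. Of 6 vitellogenin transcripts, which encode yolk proteins, 2 had estimates at both ages, with vit-4 at 4391 FPKM at day 2 and 82.0 at day 12 and vit-1 at 1244 and 52.9. Of the others, vit-2, vit-5 and transcript NM_001028103 of vit-6 were listed at 0 at day 2, where their estimates failed, and at 2790.5, 2198 and 2606 FPKM at day 12. The acyl-CoA dehydrogenase gene acdh-1 was 2424 and 1.77. Likewise pud-3 was 2819.98 and 0.324 and col-20 7529 and 6.92. Collagens had a median of −1.75 relative to all transcripts (n = 79), oxidative phosphorylation −1.43, muscle genes −1.11, vacuolar ATPase −0.93, intestine markers −0.87, lipid metabolism −0.70, immunity −0.69, proteases −0.67 and antioxidant genes −0.62, each below the 3rd percentile of matched random lists. Cytochrome oxidase gene cox-6C was 1877 and 429.6 FPKM, troponin I gene unc-27 2904 and 326, and gst-10 655 and 31.4, and the age difference of spp-17 was −8.56 relative to the median. Insulin genes lay highest, with a median of 0.61 at the 100th percentile and ins-20 at 0.233 and 37.1 FPKM. Higher at day 12 were also asp-18 (0.540 and 517), cpr-2 (7.10 and 906), spp-9 (0.842 and 732), hsp-90 (271 and 2234), cpt-4 (2.44 and 153) and fbxa-24 (3.86 and 118). Of 17679 transcripts 2506 were higher and 2755 lower by at least 1.

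In met-1; glp-1 mutants oxidative phosphorylation, collagen, germline and sperm lists were lower at day 12, again without a test. The mutant value of day 2 listed 49 of 63 germline and 55 of 89 sperm marker transcripts at an FPKM of at least 1, against 23 and 22 in the control. Oxidative phosphorylation had a median of −2.01 (34 of 37 lower by at least 1), with atp-2 at 2270.4 and 406 FPKM and atp-1 at 949.8 and 155. Collagens had a median of −1.52 (70 of 97 lower), with col-20 at 10374 and 5.79 and col-124 at 8368 and 13.9, and vit-4 was 3668 and 23.5. Germline markers (−0.77) and sperm markers (−1.26) lay at percentile 0, with the germline genes deps-1 at 9.43 and 1.04 and mex-5 at 9.70 and 1.74, and the sperm genes nspd-1 at 53.9 and 1.14 and nspd-2 at 37.4 and 1.13. Higher were F-box genes (median 0.61, 61 of 207 higher and 12 lower by at least 1) with fbxa-24 at 7.05 and 363, and insulin genes (0.73) with ins-20 at 0.239 and 79.1. Of 80 heat shock and folding transcripts 22 were higher and 11 lower by at least 1, with hsp-90 at 325 and 4422 and hsp-70 at 9.37 and 149.7. Of 14 small heat shock transcripts 4 were higher and 4 lower, with hsp-16.2 at 69.2 and 883, hsp-16.41 at 56.1 and 698 and sip-1 at 25.1 and 1.72. Of 19342 transcripts 3282 were higher and 3465 lower by at least 1.

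Setting the age change of the mutant against that of the control, in tables made separately, collagens (−0.75), proteases (−0.65), oxidative phosphorylation (−0.51) and germline markers (−0.42) had lower medians, at percentiles 0, 0, 0 and 0.22. Small heat shock proteins (0.60, percentile 99.99), F-box genes (0.46, 100th percentile), histone genes (0.38, percentile 99.7), neuropeptides (0.30) and proteasome subunits (0.27) had higher ones. The untreated animals of the isoform table, of the control's genotype, also differed from the control by 0.27 in ribosomal proteins, 0.25 in F-box genes, 0.44 in histone genes, 0.28 in small heat shock proteins, −0.22 in xenobiotic genes and −0.24 in neuropeptides. No test of the difference between mutant and control was possible, and the mutant at day 2 listed more germline and sperm markers (49 and 55 transcripts) than the control (23 and 22).

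In the authors' deposited table of untreated animals grown with the chromatin samples, acdh-1 fell from 2457 to 8.28 FPKM (log2 change −8.21, q = 9.44e-21), vit-1 from 1362 to 42.7, col-140 from 4423 to 56.0 and spp-17 from 3281 to 15.1. Rises in the authors' deposited table were led by chil-18 (8.74, q = 4.89e-15), ZK938.6 (7.93), pitr-4 (7.68), srg-62 (7.42) and the chitinase gene cht-1 (7.23). These started from day 2 values between 0.009 (ZK938.6) and 0.822 FPKM (cht-1), so their ratios rest on low values. Falls in the authors' deposited table were led by F15E11.15 (−8.54), C32H11.4 (−8.24), acdh-1, T05E12.6 (−8.08) and R07E5.4 (−7.92). Of its heat shock genes the authors' deposited table gives hsp-16.21 as 6.06, hsp-12.6 as 5.54 and hsp-70 as 3.58, each with q = 9.44e-21. At q below 0.05 the authors' deposited table calls 2208 of 16422 transcripts higher and 3094 lower at day 12, in 5188 genes. By list, the authors' deposited table has more falls than rises for collagens (36 and 2 of 82), muscle (32 and 0 of 56), oxidative phosphorylation (27 and 0 of 37), vacuolar ATPase (17 and 1 of 24), lipid metabolism (48 and 10 of 93), immunity (86 and 35 of 212), xenobiotic metabolism (68 and 33 of 163), intestine (13 and 1 of 22), proteases (9 and 1 of 19) and hedgehog-related genes (16 and 5 of 53). More rises than falls stand in the authors' deposited table for F-box genes (62 and 25 of 225), nuclear hormone receptors (39 and 19 of 250), heat shock (17 and 5 of 66), insulin (10 and 6 of 46) and ribosomal proteins (6 and 0 of 85). For small RNA genes the authors' deposited table has 8 falls and 1 rise of 37, with wago-10 at −2.59 and ergo-1 at −1.01, and for met-1 it gives 4.66 and 4.68 FPKM (q = 0.994).

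Whether the spread of age changes differed between animals labelled by met-1 state was measured as the SD of the log2 change across transcripts, although met-1 goes against the RNA interference labels. In the RNA interference table the ratio of met-1-labelled to L4440 animals was 0.987, with 0.895 to 1.033 over 16 pairings of the same 8 libraries. It differed from 1 by less than the SD of 0.046 over pairings, but includes noise between replicates. The root of the covariance of age changes that share no library leaves that noise out. This root was 1.0135 to 1.0384 in L4440 and 1.0638 to 1.07 in met-1-labelled animals, a ratio of 1.0399. These ranges did not overlap, but they rest on the same 8 libraries and were not tested. Between mutant and control the ratio was 1.089 over 16940 transcripts (1.276 in the control and 1.389 in the mutant), with a 95% interval of 1.072 to 1.108 from 1000 bootstrap draws over transcripts, which covers no spread between libraries, and the mutant at day 2 held more germline and sperm markers (49 and 55 transcripts against 23 and 22). On 11412 transcripts common to 3 tables it was 1.114, and the ratio of the control to the untreated animals of the same genotype was 1.084.

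The 5 age comparisons were set against each other. Across transcripts, which are not independent replicates, the 10 pairs of comparisons had Pearson correlations from 0.585 (L4440 with mutant, Spearman 0.591) to 0.844 (isoform table with control, Spearman 0.781), with a median of 0.676. Pairs with the isoform table rest on 11526 to 11724 transcripts and the others on 16420 to 18572, so these correlations cover unlike sets of transcripts. L4440 and met-1-labelled animals, relative to the median, shared 902 rises and 1757 falls, against 105.2 and 272.6 for independent lists. Of 11164 transcripts measured in all 5, 427 were higher and 722 lower in every comparison by at least 1 relative to its median transcript. Independent comparisons would give 0.15 and 0.55. Lower in all 5 were 40 of 135 immunity, 18 of 34 oxidative phosphorylation, 12 of 30 collagen, 27 of 142 xenobiotic, 19 of 84 lipid, 8 of 27 antioxidant and 5 of 15 protease transcripts. By Fisher's exact test over transcripts their adjusted p ran from 4.5e-15 to 0.0144. Higher in all 5 were 11 immunity transcripts (adjusted p = 0.0776), 6 xenobiotic, 1 lipid and 0 of the other 4 lists.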

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

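All tests of explanations in this part were chosen after the results were seen, whereas the interaction test was planned.

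The first pattern concerns 1 stretch of chromosome IV, left out of the comparisons, whose 1077 transcripts are listed at 0 in 6 of 8 RNA interference libraries. It stood out because the remaining libraries, both of L4440 at day 12, list 525 and 541 of them at an FPKM of at least 1. A loss of expression is argued against by the separately made isoform table, in which 422 of the 545 transcripts of the region it holds stand at an FPKM of at least 1 at day 2. Failed FPKM estimates may account for the zeros, since the same 422 transcripts are measured there and the status columns of the control and mutant tables mark the region. The first L4440 library of day 12, which holds values, has relative reads of 1.051. This is slightly above the 1.0 of the second met-1-labelled library of day 12, which is listed at 0. These estimates are close, so lower depth of the libraries that hold values cannot be told apart. Loss of expression was the one biological explanation tested.

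The second pattern is the met-1 level, which is higher in the libraries labelled met-1 RNA interference, at 80.1 and 57.1 FPKM at day 12 against 10.7 and 29.8 in L4440. The exact permutation test could not decide between exchanged and correct arm labels, since its p of 0.0556 is the smallest the design allows. Untreated control animals stood at 5.41 FPKM at day 2 and 6.34 at day 12. At both ages this is nearer the L4440 libraries than those labelled met-1 RNA interference. An exchange would put the empty-vector animals at 80.1 and 57.1 at day 12. The control values were made separately and are descriptions only, so they do not settle the question. Reads from the fed double-stranded RNA might raise met-1 in part of the gene, and transcript NM_058939 differed by only 0.21 between arms against 1.85 for NM_182042, with exact p = 0.722 and 0.0556. The second is the smallest p the design allows, so this test cannot decide, and the fed fragment is not given in the sources used here. Higher transcription of met-1 after interference stays open and was not tested.

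The third pattern is the set of transcripts called between the arms, 30 at day 2 and 92 at day 12. Reads divided differently among the transcripts of one gene do not account for the whole set, because 27 of the 30 and 78 of the 92 calls lie in genes with 1 listed transcript, but may account for the rest, since 0 of 3 calls at day 2, too few to decide, and 1 of 14 at day 12 stayed in genes with more transcripts once FPKM was summed. Transcripts without a matched symbol could count only as genes with 1 transcript. Reads divided among overlapping genes were not tested as a cause. One arm was listed at 0 in 25 of the 30 and 68 of the 92 calls. Without a status column in the RNA interference table, a failed estimate listed at 0 cannot be told apart there from absent expression. Failed estimates were therefore not tested as a cause of these calls. With only transcripts alone in their locus tested, 16 of the 30 and 28 of the 92 calls recurred. Low depth of the second L4440 library of day 12 cannot be told apart, as 32 of the 92 calls stayed without it and 49, 6 and 5 stayed without the other libraries of day 12. With 4 libraries per age only 3 splits exist, too few for a share under 0.05: at day 2 the real split gave 30 calls and the highest other 37, with 2 of 3 splits giving as many, and at day 12 the real split gave 92 and the highest other 77, with 1 of 3 giving as many. A difference due to met-1 interference stays open as untested, since met-1 itself goes against the labels.

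The age change differed between arms in 70 transcripts by the interaction test, whose direction is drawn from labels that met-1 goes against. This count was 9 to 17 without 1 of 7 of the libraries, 74 without the first L4440 library of day 12, 14 with a pseudocount of 0.1 and 7 with the replicate block.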

How the results depend on the processing

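Chosen after seeing the data were the settings that kept failed estimates, summed FPKM per gene, kept protein-coding transcripts only or transcripts alone in their locus only, scaled to equal summed FPKM, or normalized by quantiles before camera; the others were planned. Among age calls in the RNA interference table, for L4440 5545 became 3470 with centring, 3475 for transcripts alone in their locus, 3332 with equal summed FPKM, 2603 with only the 2 groups in the fit and 2846 to 4828 when 1 library was left out. For met-1-labelled animals 5835 became 3841, 3609 and 3816 in the first 3 of these settings and 2477 to 5531 without 1 library. Between arms at day 2, 30 calls became 19 with a pseudocount of 0.1, 8 with a 5 FPKM filter, 2 for protein-coding transcripts, 92 with only the 2 groups and 2 to 37 without 1 library. At day 12, 92 calls became 147 with no filter, 18 with a 5 FPKM filter, 744 with failed estimates kept at 0, 28 for protein-coding transcripts, 38 for those alone in their locus, 4 with only the 2 groups and 11 to 169 without 1 library. For the interaction 70 calls became 14 with a pseudocount of 0.1, 109 with no filter, 9 with a 5 FPKM filter, 611 with failed estimates kept, 8 for protein-coding transcripts, 20 for those alone in their locus and 9 to 74 without 1 library. Of the calls in the authors' deposited table, 5302 became 3271 with an absolute log2 change of at least 1. Fewer transcripts were tested under the stricter filters and subsets. With failed estimates kept, 482 of the 594 lower calls at day 12 and 461 of the 520 lower calls of the interaction were failed transcripts, as were 0 of the higher ones. For the other changes, including the other calls added there, the cause was not tested. Where 1 library was left out, the lone sample of its group was assumed to vary like the other groups.

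The replicate block gave 2 calls at day 2, 50 at day 12 and 7 for the interaction. The deviations of same-numbered libraries correlated from −0.06 to 0.13, highest between the arms at day 2. Splitting the libraries of day 2 by replicate number gave 37 calls, against 30 between the arms. At day 12 that split gave 77 calls, against 92. Whether the numbers pair the libraries is therefore not settled, and the block counts are a hint only. No paired analysis was possible because the control, mutant and isoform tables hold 1 value per age, so the block, leaving out a library and eBayes without trend were not run on them.

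The spread ratio of 0.987 between arms was 0.855 to 1.079 without 1 library, 1.0412 with the median absolute deviation, 1.0399 from covariances, 1.0095 with quantile normalization and 0.833 with failed estimates kept, so it lay on either side of 1. The mutant to control ratio of 1.089 was 1.025 with a pseudocount of 0.1, 1.1088 with no filter, 1.156 with the median absolute deviation and 1.1086 for protein-coding transcripts. The median correlation of 0.676 was 0.546 with a pseudocount of 0.1, 0.6365 with no filter, 0.726 with a 5 FPKM filter and 0.6655 to 0.6786 without 1 library; the cause was not tested. With an estimated correlation the lists called went from 13 to 1 and 12 to 1 for the age comparisons of L4440 and met-1-labelled animals, from 2 to 0 and 11 to 0 between arms at day 2 and day 12, and from 1 to 0 for the interaction, for which the replicate block in camera gave 5 and quantile normalization 4.

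Of single transcripts, math-33 turned from higher to −0.1702 and sca-1 to −0.0021 between arms at day 12 with FPKM summed per gene, and to −0.1762 and −0.008 when centred as well. The other named transcripts kept their direction. Of 1027 values of named age changes 1019 kept their side of the threshold and 8 lost it, and without 1 library 28 of 606 lost it. Of 638 values between arms or of the interaction 539 kept it, 94 lost it and 1 gained it, and without 1 library 142 of 340 lost it. List tests kept their side in 331 of 390 values, lost it in 43 and gained it in 16. Depth limits the second L4440 library of day 12 most, at 0.355 relative reads.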

Other observations

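The transcripts in this part outside the rule for named genes were chosen after their values were seen, and no test was made on them, since the mutant and control tables hold 1 value per age for both libraries together and were made separately. At day 2 the met-1; glp-1 mutants listed 55 of 89 sperm marker transcripts at an FPKM of at least 1 with a sum of 737 FPKM, against 22 transcripts and 371 in the glp-1 control. At day 12 the numbers were 25 and 423 in the mutant and 16 and 295 in the control, and the 8 RNA interference libraries listed 21 to 26. The sperm gene nspd-1 was 53.9 FPKM at day 2 and 1.14 at day 12 in the mutant, against 0.796 and 0 in the control, and nspd-2 was 37.4 and 1.13 against 1.74 and 0.583. Major sperm protein gene msp-50 was 7.51 and 0.326 in the mutant and 0.614 and 0 in the control, and spe-19 was 6.12 and 4.02 against 0.079 and 0.199. These families share sequence, so single members are uncertain.

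Germline and oocyte markers showed the like difference at day 2. Of 63 transcripts the mutant listed 49 at an FPKM of at least 1 with a median of 2.28 FPKM, against 23 and 0.258 in the control. At day 12 the mutant listed 30 and the control 20.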
